A study of Mus musculus with 12 samples.

How the data were processed

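The series holds RNA-seq of wild-type mouse primary oligodendrocyte progenitor cells, the glial precursors that give rise to myelinating oligodendrocytes. Per the labels, cells were treated for 12 h with vehicle (DMSO), with 50 µM hemin, with 50 µM hemin plus 10 ng/mL interleukin-10 (IL-10), or with 50 µM hemin, 10 ng/mL IL-10 and 2.5 µM stattic. Hemin is the oxidised form of heme, IL-10 is a cytokine that signals through STAT3, and stattic is an inhibitor of STAT3. Each of the 4 groups had 3 libraries. The labels do not say whether replicates came from separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

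Per the labels' protocols, total RNA was made into libraries with dUTP in the second strand and sequenced as DNA nanoballs. The submitters' processing notes name CASAVA, StringTie, Bowtie2, RSEM, HISAT, Bowtie, TopHat and Cufflinks, with no version, role or order. The genome build is not given in the sources used here, so no coordinates are printed. The deposited files give, per the file headers, an expected count (an estimated, partly fractional number of reads per gene) and an FPKM value (fragments scaled for transcript length and library depth) for each gene. The authors' expected counts were taken as not normalised, since they summed to a different total in each library. Each file lists only genes with a value above 0, and a gene absent from a file was taken as 0 there. Of the 18876 genes listed in any library, 13747 were listed in all 12, and 99.1% of the symbols matched the supplied RefSeq gene table. Whether the counting used strand is not stated, so reads of antisense or overlapping genes could not be told apart.

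Expected counts were rounded to whole numbers and tested with edgeR (4.0.16, R 4.3.3). Genes were kept with filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with robust dispersions was fitted to all 12 libraries with 1 mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. After filtering, 13967 genes were tested. Values are given as CPM, counts scaled to library size with the TMM factors, as mean ± SD (n = 3), and changes as log2 fold changes with their standard errors (SE) and 95% confidence intervals (CI). For a group with no counts of a gene, fold bounds used a floor of 3 counts over the group. Floors and counting intervals cover counting error only.

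The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each of the 3 main comparisons, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups did not overlap and whose higher mean was at least 5 CPM, leaving out predicted gene models. It took 4 and 4 for the 2 secondary comparisons, and the 5 smallest p-values where no gene was called. It also took up to 4 members of each list with the smallest adjusted p, and always Hmox1, Slc7a11, Gpx4, Acsl4, Tfrc, Fth1, Socs3, Stat3, Il10ra, Il10rb, Dlk1, Pdgfra and Mbp. Some genes that the rule took are not reported here. Dlk1 was put on the AMPK list and among the genes always named because of what is known of the study, so its change is not independent evidence for a list. Of the 27 lists, the mitochondrially encoded genes had no listed member and 26 were tested. They cover heme and iron handling, NRF2 antioxidant targets, ferroptosis, AMPK and fatty acid synthesis, the IL-10 receptor and STAT pathway, STAT3-induced genes, the integrated stress response, the unfolded protein response, heat shock proteins, metallothioneins and metal transport, progenitor markers, myelin genes, cell division, cholesterol synthesis, interferon-stimulated genes, inflammatory NF-kB targets, p53 targets, hypoxia and glycolysis, immediate early genes, autophagy and lysosome, nuclear respiratory chain subunits, ribosomal proteins, and markers of microglia, astrocytes, neurons, and fibroblasts or vascular cells. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with p-values adjusted over the lists of a comparison. The estimated correlation and fry, a self-contained test, were alternatives.

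Replicate numbers come from the labels, which do not say what a shared number means. The deviations of same-numbered libraries from their group means correlated at 0.37, 0.17 and 0.61 for replicates 1, 2 and 3 between hemin with IL-10 and hemin. Between hemin with IL-10 and stattic and hemin they correlated at 0.35, 0.39 and 0.17. In these 2 comparisons each pair exceeded 0.1 and the numbers were treated as pairing the samples. In the other 3 comparisons they were not. The rule thus linked hemin to both groups with IL-10 but not those groups to each other, so it leaves open what a shared number means. The main p-values, CIs and list tests of all comparisons come from the planned fit without a block. For the 2 comparisons with paired numbers they thus leave out the pairing. Calls with the replicate number as a block are given below for all comparisons.

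The test was checked on data simulated from the real means, dispersions and library sizes, with 200 genes changed in each of 3 runs per comparison. For hemin against vehicle it recovered 10.3%, 74.0% and 89.7% of genes changed 2-fold, 4-fold and 8-fold, and 3.1% of its calls were unchanged genes. For hemin with IL-10 against hemin it recovered 5.6%, 67.2% and 86.1%, with 4.0% of its calls unchanged genes. For the stattic comparison it recovered 8.1%, 64.8% and 88.3%, with 3.9% unchanged. Recovery depends on the number of changed genes, since the adjusted threshold is stricter where fewer than 200 change. Libraries were also drawn without a length trend or pairing of replicate numbers. The absence of calls in a comparison thus does not exclude 4-fold or 8-fold changes. Simulated lists shifted 2-fold were called in 3 of 3 runs with either correlation, and of 75 other lists per comparison 0, 0 and 3 were called with the preset correlation and 0 with the estimated one. Genes were drawn independently in these simulations. They therefore cannot show how often the preset correlation gives false list calls where members vary together. Nor can they show how often the estimated correlation misses a shifted list of such members, so a call lost with it is not evidence of no shift. The alternatives included DESeq2 (1.42.0), limma-voom, TREAT against a 1.5-fold change, DESeq2 size factors, library totals alone, no filter, a filter of 50 counts in 3 libraries, limma on log2(FPKM + 1) and on log2(FPKM + 0.1), the replicate number as a block, the 6 compared libraries alone, and each library left out in turn. After the data were seen, a correction for a transcript length trend and fits without particular libraries were added. The covariance that replicate spread alone gives between 2 comparisons sharing a group, also added then, was estimated from deviations of log2 CPM (prior count 2) from the group means, with and without the covariance of same-numbered libraries, and was checked on simulated data.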

Results

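Gene expression was measured by RNA-seq in 12 libraries of mouse oligodendrocyte progenitor cells, 3 for each treatment. Expected counts summed to between 9404448 and 10266653 per library, over 15051 to 16899 listed genes. Col19a1, a collagen gene, was the gene with the most counts in each library, at 1.09% to 2.26% of the total. Replicates of hemin with IL-10 are called IL-10 replicates and those of hemin with IL-10 and stattic are called stattic replicates. Across genes, Spearman correlations between replicates were 0.980 to 0.986 for vehicle, 0.958 to 0.979 for hemin, 0.958 to 0.984 for hemin with IL-10 and 0.945 to 0.965 for hemin with IL-10 and stattic, and no pair of replicates lay within counting noise (chi-square per degree of freedom 14.6 to 176). The first principal component held 45.2% of the variance and set the 3 vehicle libraries apart from the 9 that received hemin. The second held 20.2%, and the replicate 3 library had the lowest value in each group.

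Libraries differed in how counts spread over transcript length. Genes were put in 5 groups of equal size by transcript length. In stattic replicate 3, the shortest group (median length 1322 bases) lay a median of 1.13 log2 units above the vehicle mean and the longest group (6687 bases) at -0.86. Hemin replicate 1 had the next largest difference, at 0.47 and -0.46. Each library that received hemin had the trend in this direction, with the shortest group at 0.05 to 1.13 and the longest at -0.86 to -0.09. In the vehicle libraries these were -0.05 to 0.06 and -0.01 to 0.01. In IL-10 replicate 1 the trend was weak, at 0.05 and -0.11. Its Spearman correlation of the difference from the vehicle mean with length was -0.07, as in vehicle replicate 3. The trend thus varied in size among libraries with the same hemin dose, but cannot be fully told apart from hemin treatment. Ribosomal protein genes, taken as all symbols that start with Rpl or Rps and a digit, took 9.76% of the counts in stattic replicate 3. They took 6.56% in IL-10 replicate 3 and 5.84% in hemin replicate 1. Their share was at least 3.66% in each library that received hemin and 2.67% to 3.14% in the vehicle libraries.

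**Figure D1:**
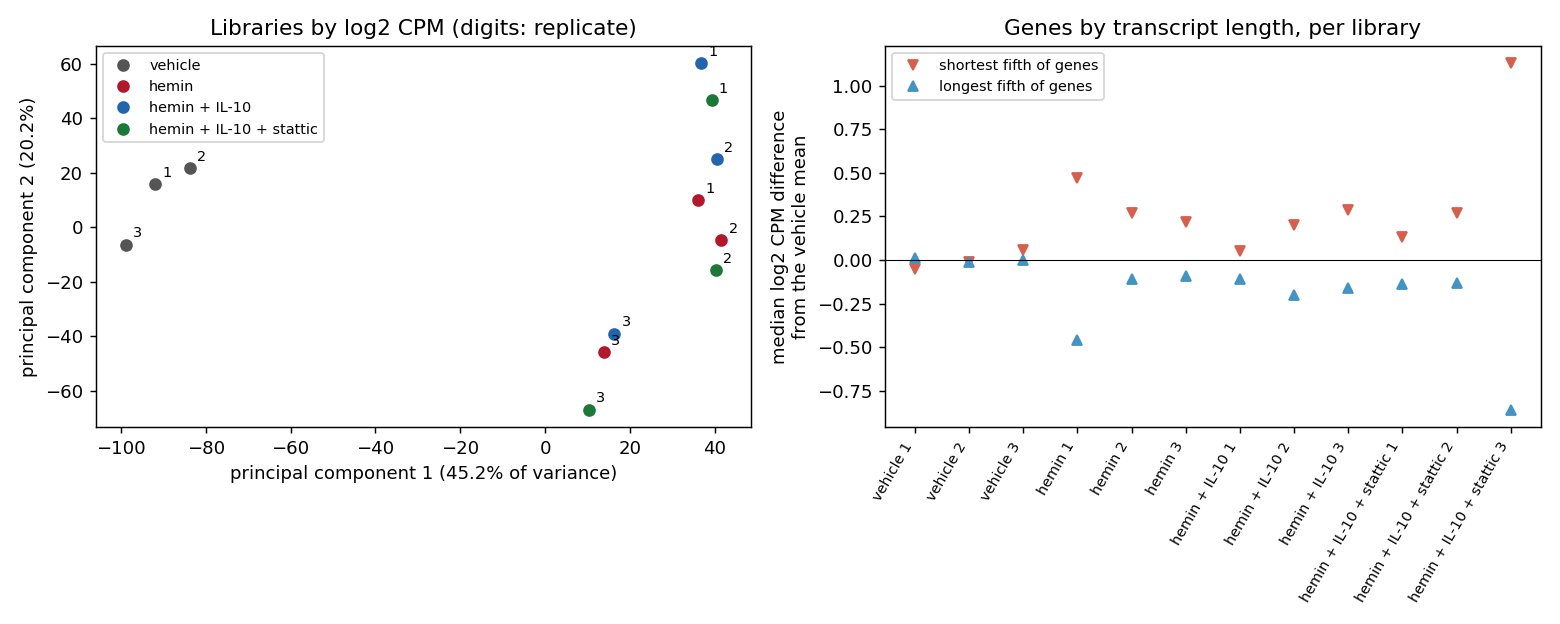
The left panel plots the 12 libraries on the first and second principal components of log2 CPM (45.2% and 20.2% of variance), with digits for the replicate, and the vehicle libraries lie apart on the first. The right panel gives, per library, the median log2 CPM difference from the vehicle mean for the shortest and longest of 5 gene groups by length, which reached 1.13 and -0.86 in stattic replicate 3.

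The comparison of hemin with vehicle asked what heme exposure did to the progenitor cells. Hmox1, which encodes the heme-degrading enzyme heme oxygenase-1, rose from 39.0 ± 15.3 to 5668 ± 2904 CPM (n = 3, log2 change 7.18, SE 0.83, adjusted p = 0.000368). Hspa1a, an inducible heat shock chaperone, had the largest rise, from 2.20 ± 0.42 to 5345 ± 2899 CPM (log2 change 11.24, SE 0.64, adjusted p = 4.56e-06). Its near-identical paralog Hspa1b rose by 9.51 log2 units, and the division of reads between the pair is uncertain. Dlk1, a membrane protein related to Notch ligands, fell from 76.6 ± 30.9 to 7.24 ± 1.51 CPM (log2 change -3.40, SE 0.43, adjusted p = 0.000586). Olig2, a transcription factor of the oligodendrocyte lineage, fell from 495 ± 141 to 75.8 ± 43.0 CPM (log2 change -2.71, SE 0.50, adjusted p = 0.00403).

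By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2917 of 13967 genes (20.9%) were called, of which 1639 were higher and 1278 lower with hemin. At least 2-fold changes were seen for 1409 higher and 875 lower genes. The groups did not overlap for 50.1% of genes, where chance gives 10%. Library totals in place of the TMM factors gave 1395 higher and 1593 lower, and DESeq2 size factors gave 1659 and 1255. limma-voom gave 1404 and 1405, and limma on log2(FPKM + 1), which changed the unit, the filter and the test together, gave 955 and 1650. Without vehicle replicates 1, 2 and 3 in turn the count was 1370, 1626 and 1472, without hemin replicate 2 it was 1309, and without the 2 libraries with the steepest length trend it was 3717.

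Several of the largest rises were of genes with no counts in vehicle. Edn1, which encodes the peptide endothelin-1, was at least 132-fold higher (12.3 ± 5.89 CPM with hemin), Hdc, the enzyme that makes histamine, at least 133-fold, Tac1, the precursor of substance P, at least 97.8-fold, Pomc, a peptide hormone precursor, at least 78.0-fold and Cxcl1, a neutrophil chemokine, at least 61.3-fold. The pseudogene Idi1-ps1 was at least 201-fold higher (adjusted p = 0.0155), but not past the threshold without vehicle replicate 1 (0.0504). Among the largest falls were Rassf10 (log2 change -3.64), Omg, a myelin-associated glycoprotein (-3.29), and Aatk, a kinase (-3.25). Gpr17, a receptor of committed progenitors, fell by 3.56 log2 units (adjusted p = 0.0272), Adamts4, a protease, by 3.49 (0.0300), Bmp4, a growth factor, by 3.37 (0.0145) and Fam205a1 by 3.15 (0.0149). Each of these 4 calls was lost in some of the fits with 1 library left out, in which the log2 change ran from -4.52 to -3.23 for Gpr17, from -3.99 to -2.57 for Adamts4, from -3.73 to -3.0 for Bmp4 and from -3.53 to -2.72 for Fam205a1. Without hemin replicate 2 the adjusted p of Gpr17 was 0.102, and its call was also lost without hemin replicate 1, vehicle replicate 1 or vehicle replicate 3. Adamts4 was at 0.112 without vehicle replicate 2 and was lost without vehicle replicate 1 or any 1 hemin library. Without vehicle replicate 1, Bmp4 was at 0.0517 and Fam205a1 at 0.0532, and Bmp4 was also lost without hemin replicate 2.

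Of 26 genes of heme and iron handling, 7 rose and 1 fell, including Hmox1, the iron exporter Slc40a1 (log2 change 7.31) and the ferritin chains Ftl1 (2.15) and Fth1 (2.33, adjusted p = 0.00815). The list test gave a median of 0.58 and an adjusted p of 0.0189, but 0.511 with an estimated correlation, 0.0952 without hemin replicate 1, 0.0537 without stattic replicate 3, 0.0522 with a length correction and 0.191 without the 2 libraries with the steepest length trend. In the last 4 of these the median was 0.58, 0.56, 0.72 and 0.58. The number of these genes that rose was 4 without vehicle replicate 2 or 3 or hemin replicate 1 or 2. The number that fell was 3 without stattic replicate 3, and 0 without any 1 vehicle library, hemin replicate 2 or 3, or IL-10 replicate 1 or 2. Of 28 NRF2 antioxidant targets, 10 rose, 11 adjusted over the list alone, and 0 fell, among them Gclc, which makes glutathione precursors (2.44), Srxn1, which restores peroxiredoxins (3.84), and Osgin1 (7.21). The median of the list was 1.07 (adjusted p = 1.98e-06, and 0.511 with an estimated correlation), and the number that rose was 5 without vehicle replicate 1 or 3 and 6 without vehicle replicate 2 or hemin replicate 1 or 2. Of 22 ferroptosis regulators, 9 rose and 0 fell, or 1 fell without stattic replicate 3 (median 0.54, adjusted p = 4.73e-05, and 0.0702 with an estimated correlation). These included Acsl4, which activates polyunsaturated fatty acids (1.68, adjusted p = 0.00336), Chac1, which degrades glutathione (4.45), Gch1 (3.54) and Ptgs2 (7.44). Several members, among them Hmox1, Fth1, Slc7a11, Chac1 and Ptgs2, are also on other lists, so this list is not separate evidence. Its higher median does not say whether ferroptosis rose. Slc7a11, the cystine transporter, rose from 20.8 ± 9.26 to 544 ± 382 CPM (4.71, adjusted p = 0.0139), but was not called without vehicle replicate 1 (0.0612) or vehicle replicate 3, with log2 changes of 4.37 to 5.20 over the fits with 1 library left out. Gpx4, which reduces lipid peroxides, was at 211 ± 28.3 against 140 ± 1.70 CPM (0.59, CI -0.03 to 1.21, adjusted p = 0.159), and the transferrin receptor Tfrc at 150 ± 30.4 against 99.4 ± 35.2 CPM (0.59, CI -0.11 to 1.30, 0.212).

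Of 22 immediate early genes, which respond rapidly to stimuli, 18 rose and 0 fell, with examples Fosb (7.51), Fos (4.70), Maff (4.12) and Atf3 (7.46). The median of this list was 3.98 (adjusted p = 1.37e-34), and it was the 1 list still called with an estimated correlation (adjusted p = 0.016). The number that rose was 18 in each fit with 1 library left out. Of 28 genes of the integrated stress response, 16 rose, 18 adjusted over the list alone, and 0 fell, including Ddit3, a transcription factor linked to cell death (3.55), and the tRNA synthetase Cars (1.62). This list had a median of 1.75 (adjusted p = 2.75e-11, and 0.425 with an estimated correlation), and 10 members rose without vehicle replicate 1. Of 18 heat shock proteins, 12 rose, 14 adjusted over the list alone, and 0 fell, with Dnajb1 at 3.21 and Hspb1 at 4.92 (median 1.65, adjusted p = 2.37e-15, and 0.0741 with an estimated correlation), and 7 rose without vehicle replicate 3. Of 18 genes of the endoplasmic reticulum unfolded protein response, 2 rose, Herpud1 (2.59) and Xbp1 (1.23), and the list was not called (median -0.06, adjusted p = 0.463). The call of Xbp1 (adjusted p = 0.0123) was lost without vehicle replicate 3 (0.0575) and without vehicle replicate 2, with log2 changes of 1.01 to 1.54 over the fits with 1 library left out.

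Of 22 inflammatory cytokines and NF-kB targets, 16 rose, 10 without vehicle replicate 3 and 17 adjusted over the list alone, and 0 fell. Microglia and macrophage markers rose in the same comparison (9 of 19, median 2.19, list adjusted p = 0.425 with an estimated correlation), with a sum of 394, 150 and 111 CPM in hemin replicates 1, 2 and 3 against 17.2 to 65.6 CPM in vehicle. Nfkbiz, a regulator of NF-kB, rose by 3.77, the cytokine Il11 by 5.08, and the chemokine Cxcl2, with no counts in vehicle, was at least 58.4-fold higher. The median was 3.34, or 3.24 with the 4 members without vehicle counts at their bounds (adjusted p = 7.2e-12, and 0.0814 with an estimated correlation). Of 19 interferon-stimulated genes, 5 rose and 1 fell, 9 and 1 adjusted over the list alone, with the chemokine Cxcl10 at 5.19 (median 1.38, adjusted p = 0.00149, 0.511 with an estimated correlation, and 0.0636 without the 2 libraries with the steepest length trend). The interferon median was 0.75 without those 2 or without hemin replicate 1 alone, and 2.12 without vehicle replicate 1. The number of interferon-stimulated genes that rose was 1 without vehicle replicate 2, vehicle replicate 3 or hemin replicate 1 and 3 without IL-10 replicate 2, and 0 fell without vehicle replicate 1 or 3, any 1 hemin library, or IL-10 replicate 1 or 2. Of 26 STAT3-induced genes, 7 rose and 0 fell, with Junb at 4.8, Cebpb at 4.92 and Nfil3 at 2.14 (median 0.57, adjusted p = 8.43e-05, and 0.425 with an estimated correlation). Socs3, a feedback inhibitor of cytokine signalling, rose from 11.7 ± 2.88 to 30.0 ± 4.44 CPM (1.35, adjusted p = 0.018), and was at 0.0785 without vehicle replicate 3 and also lost without vehicle replicate 2, hemin replicate 2 or hemin replicate 3 (log2 changes of 1.17 to 1.52 with 1 library left out). In the IL-10 receptor and STAT list, 4 of 21 genes rose and 2 fell, 5 and 2 adjusted over the list alone, and the list was not called (median 0.11, adjusted p = 0.378). The number that rose was 1 without vehicle replicate 3 and 2 without vehicle replicate 2 or hemin replicate 2, and the number that fell was 0 without any 1 vehicle library or hemin replicate 2 and 1 without hemin replicate 1 or 3. Stat6 rose by 3.76. Il10ra, the ligand-binding receptor chain, rose from 0.185 ± 0.0916 to 1.67 ± 1.24 CPM (3.08, adjusted p = 0.013, and 0.0576 without vehicle replicate 3), and Il10rb from 2.14 ± 0.366 to 4.93 ± 1.47 CPM (1.20, adjusted p = 0.0335). The Il10rb call was lost without vehicle replicate 1 (0.112), vehicle replicate 2 or 3, or hemin replicate 1 or 2. With 1 library left out the log2 change ran from 2.37 to 3.51 for Il10ra and from 0.97 to 1.40 for Il10rb. Stat3 was at 228 ± 63.0 against 278 ± 68.8 CPM (-0.28, CI -0.81 to 0.24, adjusted p = 0.436).

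Of 23 progenitor markers, 6 fell, 8 adjusted over the list alone, and 0 rose, with Olig2 called in each of the 12 fits with 1 library left out. Their median was -1.36 (adjusted p = 0.000587, and 0.511 with an estimated correlation), and the number that fell was 3 without vehicle replicate 2 and 2 without vehicle replicate 1 or 3 or hemin replicate 1 or 2. Of 25 myelin and differentiation genes, 7 fell, 8 adjusted over the list alone, and 0 rose, with Myrf, a regulator of myelin genes, at -2.83 (median -1.83, adjusted p = 6.49e-05, and 0.511 with an estimated correlation). The number of these that fell was 1 without vehicle replicate 1, 2 without hemin replicate 2, and 4 without vehicle replicate 2 or hemin replicate 1. Pdgfra, the growth factor receptor of progenitors, was at 124 ± 25.6 against 488 ± 227 CPM (-1.98, CI -3.51 to -0.44, adjusted p = 0.0651), and Mbp, myelin basic protein, at 470 ± 391 against 2162 ± 1165 CPM (-2.20, CI -4.50 to 0.09, 0.157). Of 33 cell division genes, 7 fell and 0 rose, with Rrm2, which makes DNA precursors, at -1.72 (median -0.81, adjusted p = 4.93e-05, and 0.517 with an estimated correlation). The number of these that fell was 2, 4 and 1 without vehicle replicates 1, 2 and 3, 2, 1 and 2 without hemin replicates 1, 2 and 3, 11 without stattic replicate 1 and 16 without stattic replicate 3. Of 20 genes of AMPK and fatty acid synthesis, 1 rose, or 0 without any 1 vehicle library or hemin replicate 2 or 3, and 3 fell, including Dlk1 and the kinase Camkk2 (-1.59), and the list was not called (median -0.29, adjusted p = 0.0846), although it was at 0.0466 without vehicle replicate 3 (median -0.25, and 0.412 with an estimated correlation). Dlk1 was put on this list from what is known of the study, so its count is not independent evidence.

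Among metabolic and housekeeping lists, 7 of 25 cholesterol synthesis genes rose and 0 fell, with Cyp51 at 1.72 and Insig1 at 1.90 (median 0.91, or 0.59 without hemin replicate 3, adjusted p = 0.00104, and 0.572 with an estimated correlation). The number that rose was 4, 2 and 3 without vehicle replicates 1, 2 and 3 and 3 without hemin replicate 2 or 3. Of 23 p53 targets, 7 rose, 9 adjusted over the list alone, with Plk2 at 2.58 and Perp at 2.61 (median 0.77, adjusted p = 0.0113, 0.592 with an estimated correlation, 0.0981 without hemin replicate 1 and 0.113 without the 2 libraries with the steepest length trend). The p53 median was 0.38 in both of these fits and 1.25 without hemin replicate 3, and the number that rose was 3, 4 and 2 without vehicle replicates 1, 2 and 3 and 3 without hemin replicate 2. Of 24 autophagy and lysosome genes, 5 rose, 7 adjusted over the list alone, with the autophagy receptor Sqstm1 at 3.58 and the lysosomal enzyme Gla at 1.85 (median 0.50, adjusted p = 0.00933, 0.511 with an estimated correlation, 0.0629 without hemin replicate 1 and 0.0745 without those 2 libraries, with a median of 0.43 in both). The number that rose was 2 without any 1 vehicle library or hemin replicate 1 or 2, and 8 without stattic replicate 3. Of 26 ribosomal protein genes, 5 rose, 19 adjusted over the list alone (median 0.98, adjusted p = 1.29e-05, and 0.517 with an estimated correlation). With 1 library left out the number that rose ran from 0, without any 1 vehicle library or hemin replicate 1 or 2, to 21 without stattic replicate 3. All 26 had positive changes. All genes with symbols that start with Rpl or Rps and a digit, a set other than these 26, took 5.84%, 4.76% and 4.93% of the counts in hemin replicates 1, 2 and 3. Of 25 hypoxia and glycolysis genes, 5 rose and 3 fell, 9 and 3 adjusted over the list alone, with the vasodilator peptide Adm at 4.02 and the oxygen sensor Egln1 at -1.14 (median 0.34, adjusted p = 0.105). Without hemin replicate 3 this list was at 0.0277 (median 0.46, and 0.493 with an estimated correlation). Of its members 1 rose without vehicle replicate 1 or 2, 2 without vehicle replicate 3 or hemin replicate 1 or 2, 8 without stattic replicate 1 and 9 without stattic replicate 3, and 1 fell without vehicle replicate 1 or any 1 hemin library. The 10 metallothionein and metal transport genes (1 rose, or 0 without any 1 vehicle library or hemin replicate 2 or 3, median -0.06, adjusted p = 0.714) and the 26 respiratory chain subunits (0 called, median 0.40, adjusted p = 0.12) were not called as lists. The respiratory chain list was at 0.0126 without stattic replicate 3 (median 0.38, 8 members rose), at 0.00149 without the replicate 3 library of each group (0.55, 10 rose) and at 0.0336 with log2(FPKM + 1) (0.25, 0 rose). With an estimated correlation the adjusted p in these fits was 0.507, 0.388 and 0.674.

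Of 19 microglia and macrophage markers, which belong to another cell type, 9 rose, 17 adjusted over the list alone, with the lysosomal marker Cd68 going from 4.58 ± 3.45 to 24.7 ± 7.16 CPM (2.43) and Ctss, a lysosomal protease, at 2.73 (median 2.19, adjusted p = 1.98e-06, and 0.425 with an estimated correlation). The number that rose was 3 without vehicle replicate 2, vehicle replicate 3 or hemin replicate 1, with medians of 2.45, 1.72 and 1.31. Their sum was 17.2 to 65.6 CPM in the vehicle libraries, and 394, 150 and 111 CPM in hemin replicates 1, 2 and 3. Of 17 fibroblast and vascular markers, 11 rose, 14 adjusted over the list alone, with Pecam1, an endothelial adhesion molecule, at 5.83 and the matrix gene Dcn at 6.08 (median 3.88, adjusted p = 1.01e-06, and 0.209 with an estimated correlation). The number that rose was 5, 4 and 4 without vehicle replicates 1, 2 and 3 and 6 without hemin replicate 1. The summed level of this list was 1000 CPM in hemin replicate 1 and 252 to 295 CPM in the other hemin libraries, against 76.6 to 312 CPM in vehicle. Of 20 neuron markers, 4 rose, or 2 without vehicle replicate 2 or 3, and 3 fell, 4 and 4 adjusted over the list alone, with the neurofilament gene Nefm at 4.98 and the migration gene Dcx at -1.71 (median -0.01, adjusted p = 0.56). Of 17 astrocyte markers, 1 fell, 0 adjusted over the list alone (median -0.78, adjusted p = 0.0425, and 0.595 with an estimated correlation). The number that fell was 0 without vehicle replicate 1, any 1 hemin library or IL-10 replicate 2, 2 without stattic replicate 1 or 3, and 5 without stattic replicate 2. That list call was lost without vehicle replicate 1 (0.135), vehicle replicate 2 (0.0769), hemin replicate 2 (0.0533) or stattic replicate 3 (0.0744), with a length correction (0.0522), with log2(FPKM + 1) (0.12) and without the 2 libraries with the steepest length trend (0.0891). In these 7 fits the median was -0.62, -0.71, -0.86, -0.80, -0.92, -0.84 and -0.84. The call was also lost with the replicate block (median -0.72, adjusted p = 0.0603) and with the block and length correction (-0.66, 0.0735).

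**Figure D2:**
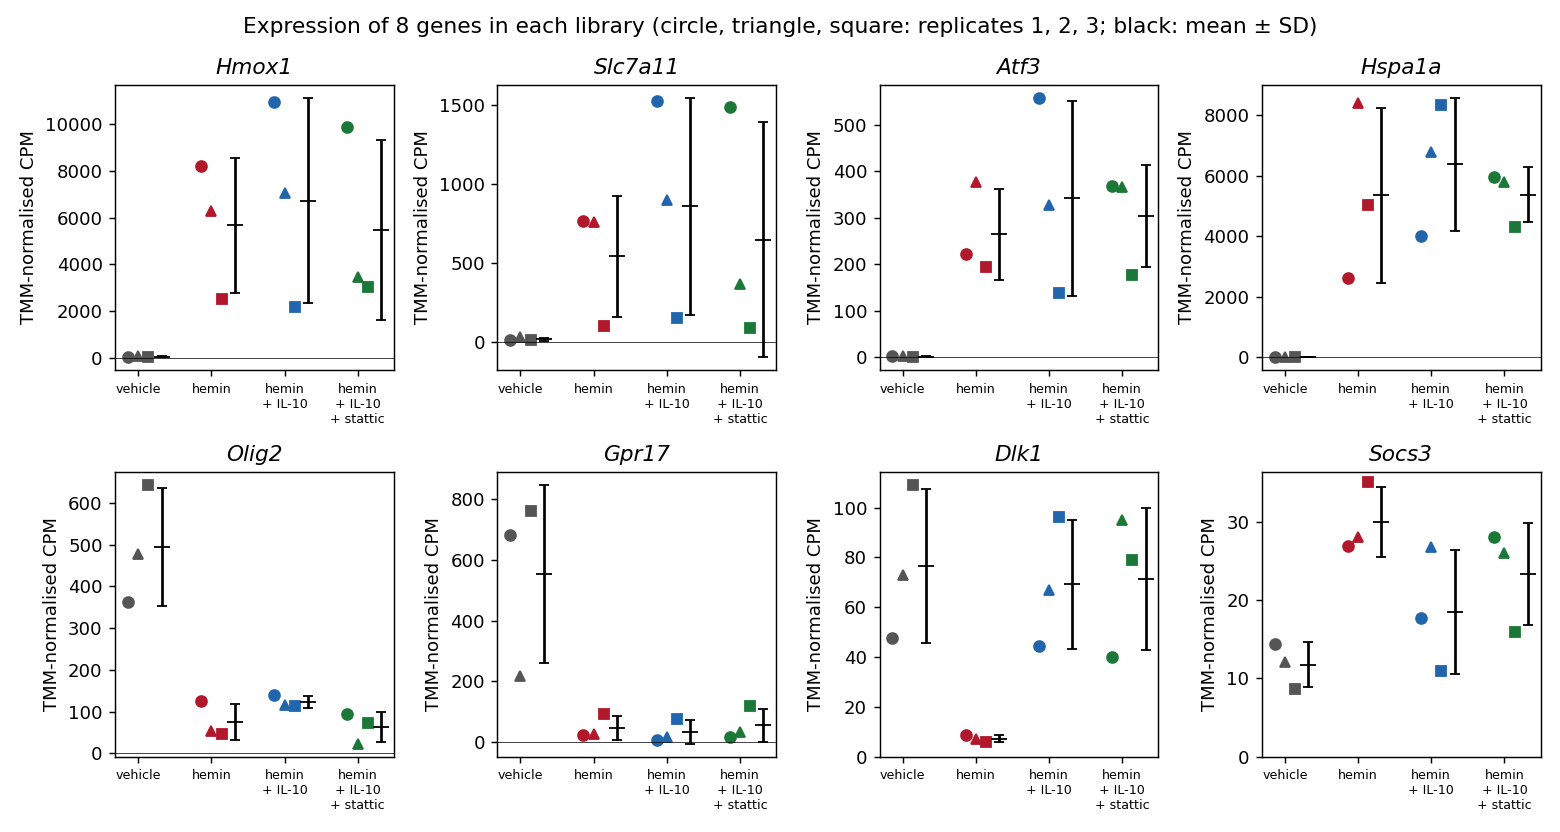
TMM-normalised CPM of 8 genes in each of the 12 libraries (circle, triangle and square for replicates 1, 2 and 3), with the mean ± SD of each group in black. Dlk1 averaged 76.6 CPM with vehicle, 7.24 with hemin, 69.2 with hemin and IL-10 and 71.3 with stattic added.

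The comparison of hemin with IL-10 against hemin alone asked what the cytokine did under heme exposure. Dlk1 averaged 69.2 ± 25.96 CPM with IL-10 and 7.24 ± 1.51 CPM without it (log2 change 3.26, SE 0.43, CI 2.33 to 4.18), with each of the 3 IL-10 libraries above each hemin library. It had the smallest p of all genes and an adjusted p of 0.0735 by edgeR's quasi-likelihood test without a block, so the main fit did not call it. With the replicate number as a block its adjusted p was 0.0287, and with DESeq2 it was 9.89e-11, the lowest over the alternatives. Without stattic replicate 1 it was 0.028 and without hemin replicate 2 it was 0.849, the highest over the alternatives. Hmox1 was at 6728 ± 4401 against 5668 ± 2904 CPM (0.25, CI -1.13 to 1.62), Slc7a11 at 860 ± 685 against 544 ± 382 CPM (0.66, CI -1.44 to 2.76) and Socs3 at 18.5 ± 7.95 against 30.0 ± 4.44 CPM (-0.70, CI -1.44 to 0.04), each with an adjusted p of 0.999.

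By edgeR 0 genes were called. An unadjusted p under 0.05 was seen for 337 of 13967 genes (2.4%), below the share of 0.05 that chance gives, and for 702 with the block. limma-voom called 0 and DESeq2 called 3: Dlk1, the histone gene H3c14 and the metal transporter Slc30a10, of which H3c14 was named after its values were seen. With the replicate number as a block, 1 gene was called (Dlk1). The groups did not overlap for 8.7% of genes, where chance gives 10%. The genes with the next smallest p-values were Lgi1, a secreted synaptic protein (log2 change -2.67, 1.62 CPM with hemin alone), Cntn2, an adhesion molecule (-1.98, 4.16 CPM), Sncaip (-1.33, 19.2 CPM) and the glutamate receptor subunit Gria1 (-1.93, 16.9 CPM), all with an adjusted p of 0.999. Slc30a10 had no counts in the IL-10 libraries and 3.17 ± 2.45 CPM with hemin, at least 30.2-fold lower with IL-10 (adjusted p = 0.999).

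No member of any list was called over all genes, while the list tests with the preset correlation called 14 of 26 lists, 4 up and 10 down. With an estimated correlation none was called, the smallest adjusted p being 0.32. Adjusted over the list alone, 7 microglia markers were lower, Dlk1 was the 1 higher gene of the AMPK list, on which it was put from what is known of the study and so is not independent evidence, and Slc30a10 was the 1 lower gene of the metal transport list. The microglia and macrophage list had the smallest p, with 18 of 19 members lower (median -1.71, or -1.0 without hemin replicate 1, adjusted p = 1.01e-17, and 0.32 with an estimated correlation). Fcer1g, an immune receptor subunit, was at 1.12 ± 0.337 against 8.11 ± 8.35 CPM and Ctss at 4.64 ± 0.915 against 17.7 ± 12.7 CPM. Fibroblast and vascular markers (median -0.84, adjusted p = 1.97e-06), neuron markers (-0.59, 2.89e-06) and astrocyte markers (-0.58, 0.000852) were lower as lists. With an estimated correlation these 3 lists had adjusted p-values of 0.32, 0.32 and 0.534. The astrocyte call was lost without IL-10 replicate 3 (median -0.21, adjusted p = 0.608), and the fibroblast call without the 2 libraries with the steepest length trend (-0.47, 0.0743). The fibroblast median was -0.54 without hemin replicate 1, and the neuron median -0.33 without IL-10 replicate 1.

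Inflammatory NF-kB targets were lower as a list (21 of 22 members, median -0.53, adjusted p = 1.55e-05), as were interferon-stimulated genes (17 of 19, -0.89, 6.48e-06). For both the adjusted p with an estimated correlation was 0.434. Without hemin replicate 1 the medians were -0.29 and -0.23 (adjusted p = 0.0993 and 0.139), and without the 2 libraries with the steepest length trend they were -0.27 and -0.22 (0.137 and 0.146). The NF-kB median was -0.34 without IL-10 replicate 3 (0.0635). The interferon median was -1.42, -1.41 and -1.43 without hemin replicate 2, hemin replicate 3 and IL-10 replicate 2. Cxcl10 was at 10.2 ± 3.13 against 27.5 ± 3.48 CPM (-1.44, SE 0.50). Cholesterol synthesis genes were lower (24 of 25 members, median -0.48, adjusted p = 1.2e-06, and 0.534 with an estimated correlation), as were cell division genes (31 of 33, -0.39, 0.000164, and 0.626 with an estimated correlation). The cholesterol median was -0.24 without hemin replicate 3, -0.20 without IL-10 replicate 1 and -0.79 without IL-10 replicate 3, and the cell division median was -0.23 without hemin replicate 2 and -0.60 without IL-10 replicate 3. Immediate early genes (median -0.12, adjusted p = 0.0019, and 0.534 with an estimated correlation) were lower as a list, but not past the threshold without hemin replicate 2 (median -0.06, 0.0792) or IL-10 replicate 3 (0.03, 0.699). Their median was -0.29 without hemin replicate 1 and -0.39 without IL-10 replicate 1. Progenitor markers (-0.36, 0.0109, and 0.625 with an estimated correlation) were lower as a list as well, but not past the threshold without hemin replicate 3 (-0.03, 0.43), IL-10 replicate 1 (-0.11, 0.415) or IL-10 replicate 2 (-0.16, 0.119). Without IL-10 replicate 3 their median was -1.02.

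The lists with higher values were the integrated stress response (28 of 28 members, median 0.45, adjusted p = 6.99e-06), heat shock proteins (16 of 18, 0.34, 0.000164), p53 targets (20 of 23, 0.47, 0.0019) and NRF2 targets (25 of 28, 0.29, 0.0164). With an estimated correlation their adjusted p-values were 0.59, 0.434, 0.625 and 0.847. Without IL-10 replicate 1 the medians of the integrated stress response, p53 targets and NRF2 targets were -0.04, 0.01 and -0.10 (adjusted p = 0.596, 0.715 and 0.445), and without hemin replicate 3 they were 0.18, 0.19 and -0.07 (0.19, 0.44 and 0.43). Without IL-10 replicate 3 they were 0.73, 0.86 and 0.65. The NRF2 list was also lost without IL-10 replicate 2 (0.23, 0.123), and without hemin replicate 1 its median was 0.70 and that of p53 targets 0.75. Without hemin replicate 2 the medians were 0.69 for the integrated stress response and 0.69 for heat shock proteins. STAT3-induced genes (median -0.08, adjusted p = 0.325) and the IL-10 receptor and STAT pathway (-0.12, 0.088) were not called. Both were lower as lists without IL-10 replicate 1 (medians -0.26 and -0.21, adjusted p = 0.00354 and 0.0107). STAT3-induced genes were also lower without hemin replicate 3 (-0.19, 0.0201) or IL-10 replicate 2 (-0.22, 0.0411), with adjusted p-values from 0.32 to 0.708 with an estimated correlation in these fits.

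The comparison of stattic, IL-10 and hemin with IL-10 and hemin asked what STAT3 inhibition added. Dlk1 was at 71.3 ± 28.4 CPM with stattic and 69.2 ± 25.96 CPM without it (log2 change 0.04, SE 0.38, CI -0.79 to 0.88, adjusted p = 0.988). Socs3 was at 23.3 ± 6.48 against 18.5 ± 7.95 CPM (0.34, CI -0.40 to 1.08), Hmox1 at 5454 ± 3852 against 6728 ± 4401 CPM (-0.30, CI -1.68 to 1.07) and Mbp at 2450 ± 2728 against 704 ± 314 CPM (1.80, CI -0.46 to 4.06). By edgeR 0 genes were called, with a smallest adjusted p of 0.921, and 0 were called by DESeq2 and limma-voom. An unadjusted p under 0.05 by edgeR was seen for 523 of 13967 genes (3.7%), below the share of 0.05 that chance gives. The groups did not overlap for 5.4% of genes, where chance gives 10%. Among the 5 smallest p-values were those of Plekhb1 (1.32, 159 against 63.6 CPM), Anln, a cytokinesis protein (-0.94, 17.6 against 33.9 CPM), Inpp5d, a phosphatase of immune cells (2.98, 5.06 against 0.632 CPM), and Jakmip1 (1.89, 4.77 against 1.27 CPM).

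The list tests with the preset correlation called 11 of 26 lists, 7 up and 4 down, and none with an estimated correlation, where the smallest adjusted p was 0.635. Over all genes 0 members were called, and adjusted over the list alone 11 microglia markers were higher. Microglia and macrophage markers were higher in 18 of 19 members (median 1.77, adjusted p = 3.53e-16, and 0.635 with an estimated correlation), with Laptm5 at 15.9 ± 7.23 against 3.67 ± 1.91 CPM. Myelin genes were higher in 25 of 25 members (1.06, 5.79e-08), among them Cnp, a myelin enzyme, at 1057 ± 573 against 357 ± 209 CPM. The adjusted p of the myelin list was 0.878 with an estimated correlation, and without stattic replicate 2 its median was 0.35 (0.126). Neuron markers were higher as a list (0.55, 0.000567), with 0.878 with an estimated correlation and a median of 0.43 without stattic replicate 2 (0.33). STAT3-induced genes were not called (0 of 26 members, median 0.01, mean 0.06, test direction down, adjusted p = 0.882), although they were lower as a list without IL-10 replicate 3 (median -0.08, adjusted p = 0.0305, and 0.618 with an estimated correlation). The IL-10 receptor and STAT list was not called either (0 of 21 members, median 0.11, adjusted p = 0.922). Autophagy genes (0.22, 0.00267) had 0.878 with an estimated correlation, a median of 0.00 without IL-10 replicate 3 (0.586) and of 0.34 without IL-10 replicate 1.

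Ribosomal proteins (26 of 26 members higher, median 0.58, adjusted p = 5.2e-08), cholesterol synthesis (0.68, 5.6e-07) and respiratory chain subunits (0.49, 0.000216) were higher as lists. Each had an adjusted p of 0.878 with an estimated correlation. Without stattic replicate 3, the library with the steepest length trend, the medians were -0.03, 0.06 and -0.13, and the respiratory chain list was called in the other direction (adjusted p = 0.00347, and 0.741 with an estimated correlation). With a length correction the ribosomal protein median was 0.06 (0.356) and the respiratory chain median -0.03 (0.787). The respiratory chain median was 0.74 without stattic replicate 1. Cell division genes (-0.14, 0.000831), the integrated stress response (-0.38, 0.000635), p53 targets (-0.44, 0.00266) and heat shock proteins (-0.28, 0.0153) were lower as lists, each with an adjusted p of 0.878 with an estimated correlation. The median of the first was 0.14 without stattic replicate 1 (0.787), 0.11 without IL-10 replicate 3 (0.263), 0.03 without stattic replicate 2 (0.0531), -0.83 without stattic replicate 3, -0.23 without IL-10 replicate 1 and -0.24 without IL-10 replicate 2. Without stattic replicate 3 the medians of the other 3 were -0.16, -0.15 and -0.09 (0.49, 0.515 and 0.596), and without IL-10 replicate 1 they were 0.05, 0.03 and -0.21 (0.811, 0.737 and 0.0723). The integrated stress response and p53 medians were -0.69 and -0.74 without IL-10 replicate 3, and -0.75 and -0.97 without stattic replicate 1. Heat shock proteins were also lost without IL-10 replicate 2 (-0.25, 0.0825), and p53 targets without stattic replicate 2 (-0.32, 0.126).

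**Figure D3:**
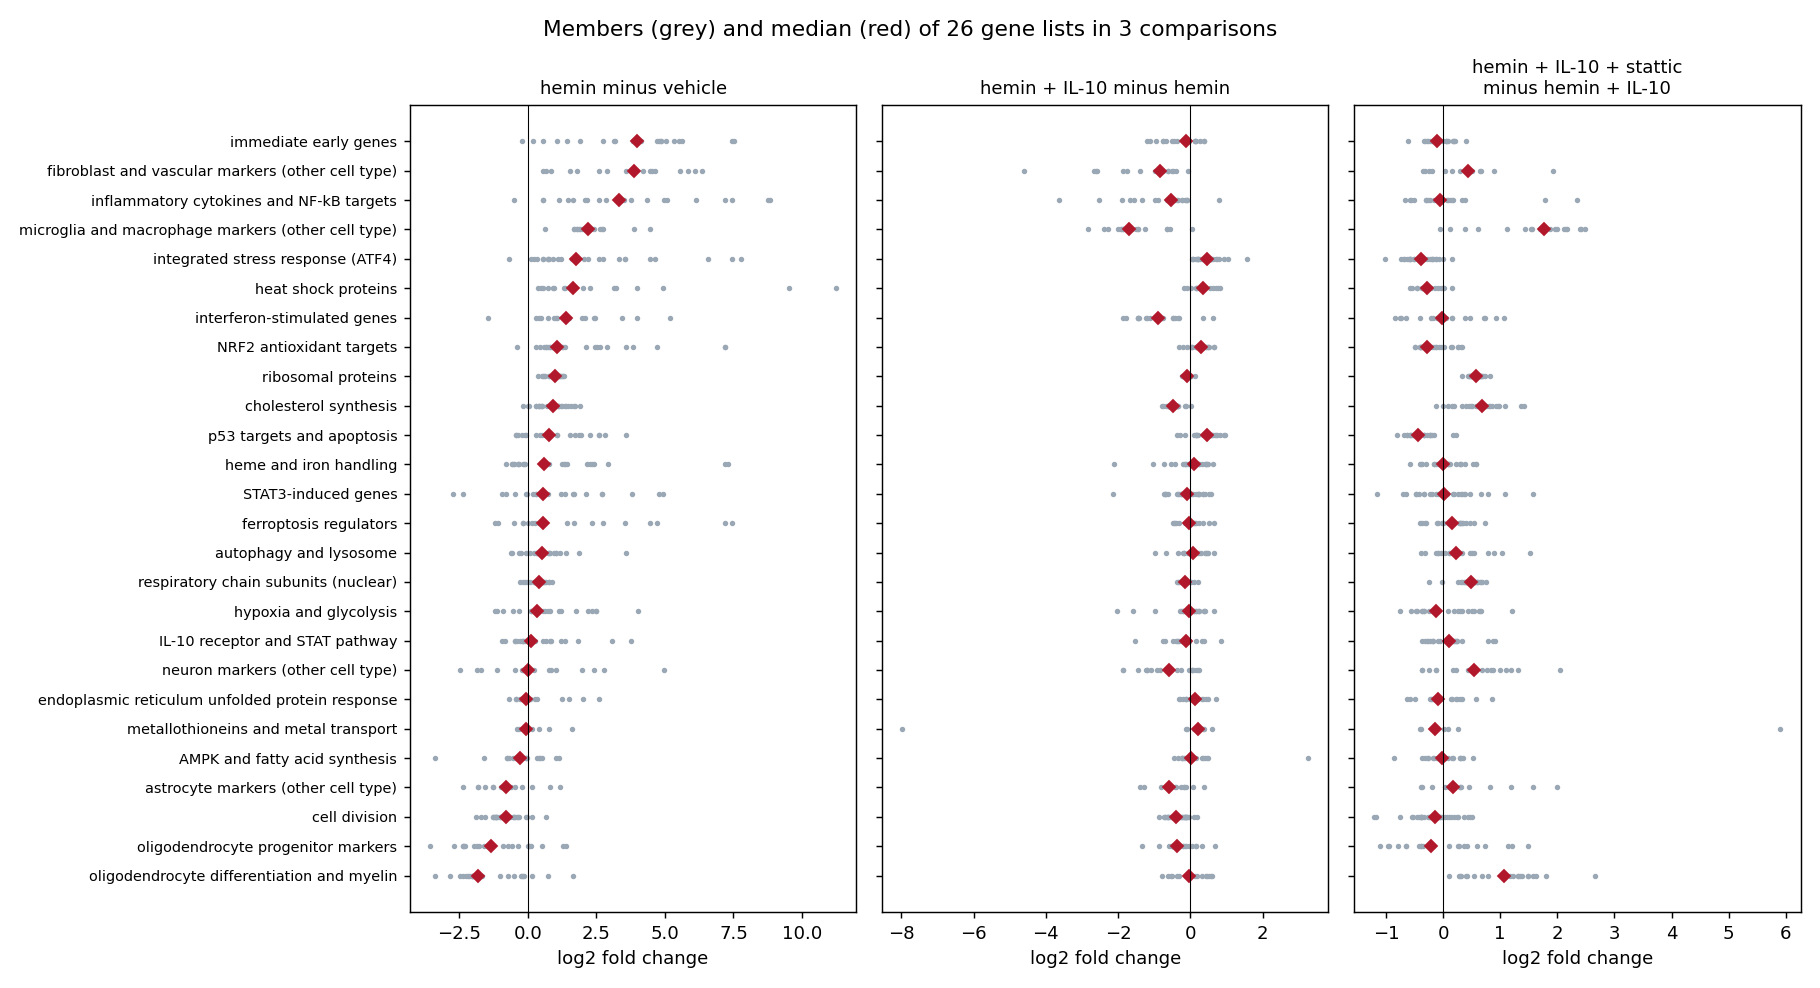
Log2 fold changes of the members (grey) and median (red) of 26 gene lists in the 3 main comparisons, ordered by the median with hemin, with separate horizontal scales. Genes with no counts in 1 group are drawn at their fitted value, and the medians run from -1.83 to 3.98 for hemin, from -1.71 to 0.47 for IL-10 and from -0.44 to 1.77 for stattic.

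Hemin with IL-10 was also compared with vehicle. Dlk1 was at 69.2 ± 25.96 against 76.6 ± 30.9 CPM (log2 change -0.15, CI -0.98 to 0.69, adjusted p = 0.822). Hmox1 rose by 7.43 (adjusted p = 0.000393), Slc7a11 by 5.37 (0.00908), Acsl4 by 1.28 (0.0113) and Fth1 by 2.17 (0.0109), and the largest rises were of Hspa1a (11.49) and Hspa1b (9.87). Myod1, a muscle transcription factor, had 2 counts in vehicle and 53.3 ± 46.1 CPM with IL-10, a ratio of 842 with a counting interval of 233 to 6960, and Hdc was at least 87.9-fold higher. The largest falls were of Gpr17 (-4.07), Rassf10 (-3.86), Bmp4 (-3.76) and Fam205a1 (-3.60). Without IL-10 replicate 2 the adjusted p of Gpr17 was 0.0734, against 0.0182 with all libraries, and that of Fam205a1 was 0.0513, against 0.0099. The Gpr17 call was also lost without vehicle replicate 1 or IL-10 replicate 1. Acsl4 was at 0.0516 without vehicle replicate 1 and Fth1 at 0.0506 without vehicle replicate 3. With 1 library left out the log2 changes ran from -5.66 to -3.59 for Gpr17, -4.25 to -3.33 for Fam205a1, 1.19 to 1.46 for Acsl4 and 1.91 to 2.46 for Fth1. Of 13967 genes, 2927 were called, 1696 higher and 1231 lower. Scaling by library totals gave 1317 and 1665, and moved the median of all genes from 0.00 to -0.13. The count was 1202 without vehicle replicate 1, 1468 without vehicle replicate 3, 1697 without vehicle replicate 2, 1766 without IL-10 replicate 1, 1272 without IL-10 replicate 2 and 4546 without the 2 libraries with the steepest length trend. With the preset correlation 16 lists were called, 12 up and 4 down, and 2 held with an estimated correlation: immediate early genes (median 3.89, adjusted p = 0.0306 with an estimated correlation) and heat shock proteins (2.16, 0.0382).

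The 2 comparisons with vehicle shared 2199 calls in the same direction, 1281 higher and 918 lower, where independent lists would share 199 and 113. They use the same vehicle libraries. The correlation of their log2 changes across genes, which are not independent replicates, was 0.93 (covariance 1.63), against 0.49 (covariance 0.11) and 0 shared calls in simulations with no effect. In simulations where IL-10 added nothing to hemin it was 0.94 (covariance 1.80), with 2630 shared calls. The 3 vehicle libraries could not be split with at least 2 on each side, so part of the excess may come from the shared controls. On mean log2 CPM the covariance was 1.034. The replicate spread alone gave 0.055 for independent libraries and 0.067 with same-numbered libraries paired. These values, which have no interval, argue against the replicate spread of the shared controls as the whole source.

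Whether IL-10 moved the genes that hemin moved was tested by correlating their changes. Of the 2917 genes called for hemin, 0 were called for IL-10 in either direction by edgeR. Across 13967 genes the log2 changes correlated at -0.21 (covariance -0.14). Both comparisons use the hemin libraries, which gave -0.17 (range -0.19 to -0.15, covariance -0.11) in 20 simulations with a hemin effect alone, in which libraries were drawn without regard to replicate number. On mean log2 CPM the covariance was -0.103, and the replicate spread alone gave -0.095 for independent libraries and -0.054 with same-numbered libraries paired. For stattic against IL-10 the correlation was -0.55 (covariance -0.13), against -0.50 (range -0.53 to -0.47, covariance -0.11) in simulations with no group differing. On mean log2 CPM its covariance was -0.106, and the replicate spread alone gave -0.098 for independent libraries and -0.035 with same-numbered libraries paired. These references rest on 3 libraries per group and have no interval. The correlation for stattic was -0.21 without the 2 libraries with the steepest length trend.

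Stattic, IL-10 and hemin were last compared with hemin alone. Dlk1 was at 71.3 ± 28.4 against 7.24 ± 1.51 CPM (log2 change 3.30, SE 0.43, CI 2.37 to 4.22, adjusted p = 0.0655), with 0.0259 under the replicate block and a range over the alternatives from 6.21e-11 with DESeq2 to 0.866 without hemin replicate 3. It was at 0.0189 without stattic replicate 1. By edgeR 0 genes were called, while DESeq2 and the block each called 1 (Dlk1) and limma-voom 0. An unadjusted p under 0.05 by edgeR without the block was seen for 481 genes (3.4%), below the share of 0.05 that chance gives. The next smallest p-values were of Anln (-1.02), Tspan17 (1.5), Urm1 (1.01) and Pcdh18 (-1.16). With the preset correlation 11 lists were called, 4 up and 7 down, and 0 with an estimated correlation. Cell division genes had the smallest p, with 30 of 33 members lower (median -0.45, adjusted p = 5.24e-13, and 0.506 with an estimated correlation).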

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

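The length correction, alone or with the block, the block within the 6 compared libraries, and the fits without particular libraries (the 2 with the steepest length trend, or the replicate 3 libraries) were chosen after the data were seen, as was the covariance from the replicate spread. No named gene that was called changed direction under any alternative that tested it. For hemin against vehicle, 90.5% of the calls were shared with the length-corrected fit and 88.3% with the fit without the 2 libraries with the steepest length trend. The share was 72.2% with log2(FPKM + 1), 73.7% without the replicate 3 libraries and 42.9% with TREAT. With 1 library left out it ran from 44.2% without hemin replicate 2 to 99.9% without stattic replicate 3. The count of 2917 became 1251 with TREAT, 949 at an adjusted p under 0.01 and 4788 with the block and length correction, and 1309 to 4256 with 1 library left out. For hemin with IL-10 against vehicle, 2927 became 1207 with TREAT, 944 at 0.01, 5021 with the block and length correction, 4544 with the block in 6 libraries, 4546 without the 2 libraries, and 1202 to 4227 with 1 left out. For hemin with IL-10 against hemin, 0 became 3 with DESeq2 and 1 with no filter, with the block, and with the block and length correction, and 0 to 1 with 1 library left out. For stattic against hemin, 0 became 1 under each of these 4 settings, and 0 to 1 with 1 left out. For stattic against hemin with IL-10 it was 0 throughout. TREAT and the stricter threshold ask for more by construction. The cause of the other differences was not tested.

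The replicate block gave 4000 calls for hemin against vehicle, 3929 for hemin with IL-10 against vehicle and 0 for stattic against hemin with IL-10, where same-numbered libraries did not all correlate over 0.1 (0.15, 0.08 and 0.32; 0.05, 0.19 and 0.37; 0.64, -0.05 and 0.48). Of 12 libraries, 9 correlated best with their own number. Where the numbers paired the samples, the block gave 1 call each (Dlk1), or 0 within the 6 compared libraries, and changed no other call of a gene or list, except that for stattic against hemin the respiratory chain subunits (adjusted p = 0.0328 without the block) and the astrocyte markers (0.0439) were both at 0.0839 with it. Called lists under the block numbered 18, 14, 12, 16 and 9 in the order of the next paragraph, and the correlations were -0.21 (IL-10) and -0.56 (stattic).

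Called lists numbered 19, 14, 11, 16 and 11 for hemin, IL-10, stattic, hemin with IL-10 against vehicle, and stattic against hemin. With an estimated correlation they were 1, 0, 0, 2 and 0, and with fry 11, 0, 0, 9 and 0. With 1 library left out they ranged from 16 to 20, 13 to 15, 7 to 12, 15 to 18 and 9 to 17, and for stattic 7 without the 2 libraries. The correlation of -0.21 for IL-10 became -0.31 with no filter, -0.20 with FPKM, -0.19 with the length correction, -0.25 without the 2 libraries and -0.32 to -0.18 with 1 left out. That of -0.55 for stattic became -0.49, -0.53, -0.21 without the 2 libraries, and -0.74 to -0.30 with 1 left out. Depth of 9404448 to 10266653 counts limits genes near the floor, such as Il10ra.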

Other observations

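The tests of gene ontology terms, of other cell types and of stattic for Dlk1, of single libraries for the microglia markers and of other splits were chosen only after the results were seen, and the tests with the length trend removed use a correction added after the data were seen. In this section, ranges in brackets after list medians are 95% bootstrap intervals over the members of the list. They take members as independent and do not measure the spread between libraries.

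Beyond the fixed lists, gene ontology terms attached to the genes in the deposited files were tested for enrichment among the hemin calls (hypergeometric test against 13211 annotated tested genes, 1457 terms of 15 to 300 genes per direction, Benjamini-Hochberg adjustment). The test takes genes as independent. It was run on the calls of the main fit alone, with no length correction and no library left out. Among higher genes 107 terms passed. Inflammatory response held 67 called genes of 200 where 23.4 were expected (adjusted p = 3.54e-13), immune response 41 of 103 (expected 12.1, 1.8e-10), transforming growth factor beta receptor signaling 25 of 73 (expected 8.55, 8.84e-05) and chemotaxis 22 of 65 (expected 7.61, 0.000331). Among lower genes 5 terms passed. Synapse assembly held 17 of 47 (adjusted p = 0.00061), repair by homologous recombination 20 of 71 (0.0028) and DNA replication 24 of 118 (0.0472). Of 19 microglia and macrophage markers, 9 rose with hemin and 3 without hemin replicate 1 (median 2.19 and 1.31, adjusted p of the list 1.98e-06, and 0.425 with an estimated correlation), with a sum of 17.2 to 65.6 CPM in the vehicle libraries and 111 to 394 CPM in the hemin libraries. Of 17 fibroblast and vascular markers, 11 rose (median 3.88, adjusted p of the list 1.01e-06, and 0.209 with an estimated correlation), or 6 without hemin replicate 1, in which their sum was 1000 CPM against 252 to 295 in the other hemin libraries and 76.6 to 312 in vehicle.

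Dlk1 was lower with hemin alone than in the other 3 groups. With the length trend removed, its change with IL-10 was 3.32 (CI 2.44 to 4.21) against 3.26 before, which argues against that trend as the whole cause. Other cells in the libraries with more Dlk1 would raise their markers there, but the highest median of the 4 other cell-type lists was -0.58 (-0.66 to -0.18) with IL-10. In vehicle, 17 of 17 astrocyte, 19 of 20 neuron, 12 of 19 microglia and 9 of 17 fibroblast and vascular markers averaged at least 1 CPM. A small share of other cells might therefore not move these medians. Vehicle was not compared with hemin for this explanation, which stays open. For an action of IL-10 that stattic blocks at 2.5 µM, a Dlk1 change of -1.63 log2 units or further was asked, a bound set after the results were seen. The change of Dlk1 with stattic was 0.04 (CI -0.79 to 0.88), which argues against a block of that size. A smaller block is not excluded. STAT3-induced genes had a median of 0.01 with stattic (adjusted p = 0.882), and were not called as a list with IL-10 either. Whether IL-10 acted through STAT3 in these cells, and whether stattic blocked STAT3, thus stays open. For IL-10 against hemin, edgeR did not call Dlk1 in the main fit, but called it with the replicate number as a block.

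Microglia and macrophage markers had a median of -1.71 with IL-10 and 1.77 with stattic, with 0 of 19 members called over all genes and list calls lost with an estimated correlation (adjusted p = 0.32 and 0.635), and of the 19, 0 are on another list and 12 averaged at least 1 CPM in vehicle. With the length trend removed the medians were -1.65 (-1.77 to -1.29) and 1.55 (1.28 to 1.87), which argues against that trend as the whole cause. Without hemin replicate 1 the first was -1.0 (-1.15 to -0.61), and without stattic replicate 2 the second was 1.48 (0.74 to 1.70), so the part of single libraries stays open. Summed over the list, CPM were 394, 150 and 111 with hemin, 101, 60.6 and 53.7 with IL-10 and 165, 315 and 192 with stattic, and Lyz2, the list's most abundant gene, reached 144 CPM in hemin replicate 1. A few microglia in the cultures, in numbers that differ between libraries, may be one source, and an effect of the treatments on such cells is another that was not tested.

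Ribosomal protein genes had a median of 0.98 with hemin, with 5 of 26 called, 0 without any 1 vehicle library or hemin replicate 1 or 2, and the list at an adjusted p of 0.517 with an estimated correlation. Without hemin replicate 1 the median was 0.85 (0.72 to 0.91), which argues against that library as the whole cause. With the length trend removed it was 0.55 (0.45 to 0.71), so the trend may account for part of the difference, and the rest stays open. The trend had the same direction in each library that received hemin, so it cannot be fully told apart from hemin treatment. Its size varied among these libraries. In IL-10 replicate 1 the Spearman correlation with length was -0.07, as in vehicle replicate 3.

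Each comparison allows 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. For hemin against vehicle (2917 genes) and for hemin with IL-10 against vehicle (2927), 1 of 10 splits gave as many, the real one, and the highest other gave 0. For the other 3 comparisons the real split gave 0, so that 10 of 10 had to give as many and the count decides nothing. The highest other was 0 for IL-10 against hemin and for stattic against hemin, where the replicate numbers paired the samples. In these 2, with the replicate number as a block, the real split gave 1 call, and the 3 other splits that part all 3 pairs gave 0. The 6 splits that keep pairs together were not run with the block. For stattic against hemin with IL-10 the highest other was 1681. That split set IL-10 replicates 1 and 2 and stattic replicate 1 against IL-10 replicate 3 and stattic replicates 2 and 3, and points to a structure of the samples other than the treatment.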
